A study of Mus musculus with 12 samples.

How the data were processed

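The 6 libraries analysed were each from the tumour of 1 mouse: 3 mice that had received vehicle-treated T cells (control) and 3 that had received T cells exposed in culture to CAL-101 (idelalisib, an inhibitor of the delta isoform of phosphoinositide 3-kinase). Each library carried gene expression and surface protein tags from the same droplets, so that the 12 sample records describe 6 mice. Per the labels' protocols, libraries were made with a droplet-based 3' chemistry and a mouse cocktail of barcoded antibodies. The matrices deposited by the authors held UMI counts, unscaled, per cell for 32285 genes and 102 antibodies, of which 7 were isotype controls. Counting was done with Cell Ranger 7.1.0, per the file headers, against mm10, per the submitters' processing notes, which also name Seurat without a version. The annotation version, the cell calling and the filters on cells are not given in the sources used here; the smallest deposited cell held 500 RNA UMIs. The deposited cell tables gave each of 45477 cells a sample, 1 of 14 cluster numbers and 1 of 10 cell type labels, and the labelling method is not given in the sources used here. Of the gene identifiers, 32158 matched the mouse gene table used for names, and no coordinates were used.

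The labels T cells (32188 cells), CD8 T cells (506) and CD4 T cells (167) were merged, which left 8 classes. The T class included 2507 cells (7.63%) in clusters led by NK cell genes and 1709 in cluster 6, whose median cell held 866 UMIs with 34.9% from mitochondrial genes. Counts led with for T cells were therefore also computed on clusters 1 to 5, and those for NK cells on clusters 0, 7, 9 and 13; both alternatives were chosen after the data were seen. Of 360 cells labelled monocytes, 232 lay in cluster 10, led by neutrophil genes, and 109 in cluster 11, led by MHC class II genes, so those clusters were also compared by number.

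Cells are not replicates. RNA UMIs were summed per mouse and class and tested with edgeR 4.0.16 quasi-likelihood (TMM, filterByExpr, group as the only term) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Host classes were fitted where every mouse had at least 20 cells, which left NK cells and cells labelled monocytes. Gene lists with at least 3 measured members were tested with limma 3.58.1 camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Antibody tags were summed and tested in the same way over the 102 antibodies. Shares of cells were compared with an exact 2-sided permutation test over the 20 assignments of the 6 mice, whose smallest p is 0.1, adjusted over the classes or clusters. For shares of cells with Tcf7 or Havcr2 UMIs, each cell was thinned to 1600 UMIs, a depth that 90.7 to 94.1% of the T cells of each mouse reached. DESeq2 1.42.0 was an alternative test, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for shares and plots. Differences of effect between T and NK cells were tested with limma on the per-mouse difference of log2 CPM (prior count 2).

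The groups, tests, gene lists and the rule for naming genes were fixed before the data were examined. The rule took the 8 largest changes each way among genes past the threshold with a mean of at least 20 CPM and no overlap between the groups, without ribosomal, mitochondrial, Gm and Rik entries. To these it added up to 4 members of each list by smallest p and, in T cells, Tcf7, Slamf6, Havcr2, Pdcd1, Tox, Gzmb and Ifng. For proteins it took the 8 largest called changes each way, with named proteins such as PD-1, TIM-3, CD127 and CD44 in T cells; 1 gene and its protein are not reported here. Other filters, normalisations, a thinning of the sums, a replicate block and the omission of each mouse were tried. Doublets were scored with Scrublet in scanpy 1.11.5; its automatic threshold marked 0 to 1.61% of cells per library, so the planned removal of called doublets was not run. In its place the 2806 cells (6.17%) with the highest scores, 0.8% per 1000 cells, were left out as an alternative chosen after seeing the data.

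The edgeR test was tried on simulated counts with known changes. In each class 50 genes were changed by a log2 of 2, 100 by 1 and 50 by 0.585. The rates hold for those genes in the simulation and do not give the power or error over all genes tested. In T cells (16734 genes) it recovered 100% of genes changed by a log2 of 1 or 0.585, with 11 false calls, and in NK cells (14028 genes) 100% and 92%, with 7. In cells labelled monocytes (5906 genes) it recovered 58% of genes changed by a log2 of 2 and 4% of those changed by 1. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 13.1 to 61.8 for pairs of mice of 1 group. Counts of near-identical paralogs, such as members of the granzyme cluster or Hspa1a and Hspa1b, are uncertain where the authors' counting could split reads between them.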

Results

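Tumours of 6 Rag1-deficient mice, which make no T or B cells of their own, were profiled after transfer of CD8+ T cells. The tumours were B16-F10, a transplantable mouse melanoma, and the transferred Pmel T cells carry a receptor for a melanocyte antigen and the Thy1.1 mark. The cells had been cultured with CAL-101 or with vehicle before transfer, 3 mice in each group, and live CD45.2+ leukocytes were sorted from the tumours. Control mice 1, 2 and 3 gave 8445, 7716 and 9147 cells with 97933109, 93817716 and 90933212 RNA UMIs. CAL-101 mice 1, 2 and 3 gave 6152, 7217 and 6800 cells with 75716841, 93929471 and 85834298 RNA UMIs. The median cell held 8095, 7694 and 6767 RNA UMIs in the control mice and 7508, 8977 and 8504.5 in the CAL-101 mice. Antibody tags came to 18237209, 16262345 and 16976075 in the control and 13243299, 12748632 and 13057501 in the CAL-101 libraries. Cells with over 20% mitochondrial UMIs made up 8.72% ± 2.06 of control and 13.02% ± 2.25 of CAL-101 cells (SD, n = 3 each).

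The first question was whether the composition of the sorted leukocytes differed. T cells made up 64.9% ± 10.0 of cells in control and 80.1% ± 13.5 in CAL-101 tumours (SD, n = 3 each), and NK cells, the main host class, 32.7% ± 10.9 and 18.2% ± 13.3. The NK share was 25.6, 45.3 and 27.2% in the control mice and 33.3, 7.91 and 13.5% in the CAL-101 mice, so that the groups overlapped (exact permutation p = 0.3, adjusted p = 0.6 for T and NK cells alike). Neutrophils took 1.23% ± 1.06 and 0.479% ± 0.232 (exact p = 0.3), and cells labelled monocytes 0.837% ± 0.379 and 0.724% ± 0.121 (exact p = 0.6). Dendritic cells, which present antigen to T cells, took 0.223% ± 0.123 and 0.367% ± 0.235 of all cells (exact p = 0.5). Among host cells alone the dendritic cell share was 0.607% ± 0.168 and 2.00% ± 0.835, with no overlap between the groups (exact p = 0.1, adjusted p = 0.35). Basophils (13 cells), B cells (8) and progenitors (7) were too few to compare. No class share passed the exact test, which with 3 mice against 3 cannot go below 0.1, and edgeR on cell numbers gave adjusted p of at least 0.458. With 1 mouse left out the T cell difference ran from 9.40 (without control mouse 2) to 22.8 points (without CAL-101 mouse 1) and the NK cell difference from -8.21 to -22.0 points without the same mice. The neutrophil difference of -0.755 points was -0.153 without control mouse 1, and the dendritic cell difference of 0.145 points was 0.0115 without CAL-101 mouse 1.

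**Figure D1:**
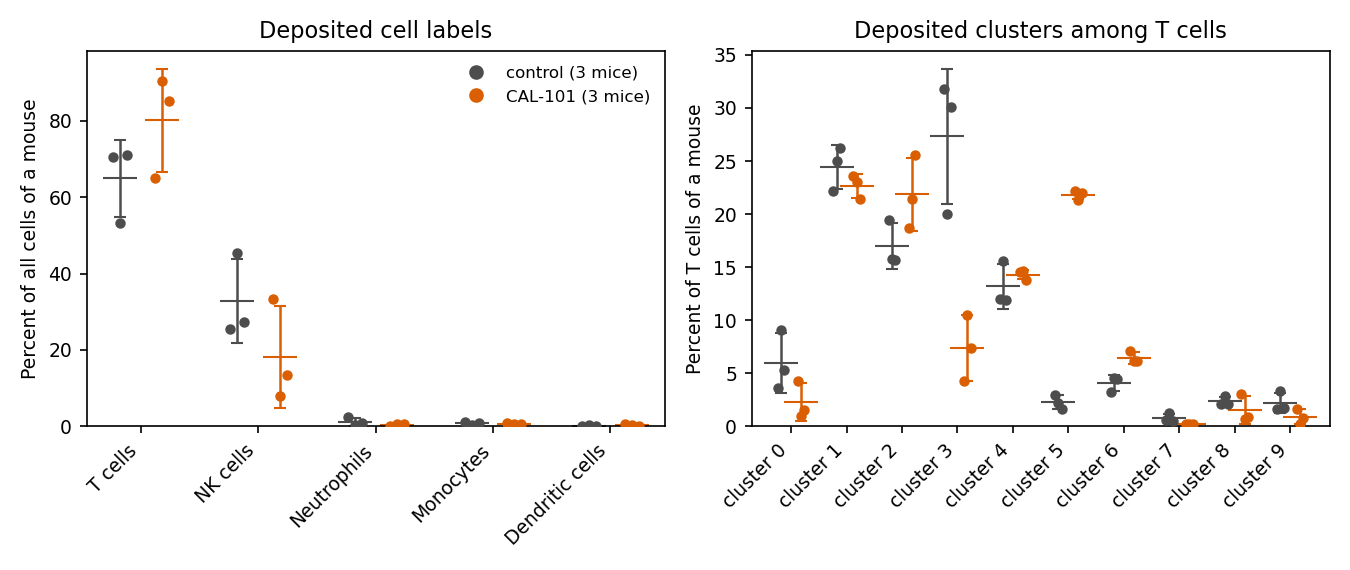
Shares of cells per mouse (percent; points are mice, bars the mean and SD of 3) by cell type class and, within T cells, by deposited cluster, for control and CAL-101 tumours. Class shares overlapped, while within T cells cluster 3 was at 27.3% and 7.39% and cluster 5 at 2.30% and 21.8% in control and CAL-101 tumours.

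Whether the pretreated T cells took up progenitor-like or terminal states was asked first by cluster. Cluster 5, with Inpp4b, Tox, Dapl1, Jchain and Igkc among its leading genes, held 2.30% ± 0.679 of T cells in control and 21.8% ± 0.439 in CAL-101 tumours (SD, n = 3 each). Cluster 3, with Ifitm1 and the chemokine and cytokine genes Ccl3, Ccl1, Ifng and Ccl4 among its leading genes, held 27.3% ± 6.39 and 7.39% ± 3.08. Both shares were apart in all 6 mice (exact permutation p = 0.1, adjusted p = 0.25), and edgeR on cell numbers gave log2 ratios of 3.25 (adjusted p = 0.00038) and -1.88 (adjusted p = 0.0191). Of the 10 leading genes of each cluster, 7 for cluster 5 and 9 for cluster 3 also differed between the groups inside another T cell cluster, so these shares are not separate from the gene differences below. Cluster 6, of low UMI number and high mitochondrial share, held 4.10% ± 0.736 and 6.45% ± 0.556 of T cells. Cluster 7, led by granzyme and NK cell genes, held 0.797% ± 0.405 and 0.230% ± 0.0185. Both were also without overlap (exact p = 0.1, adjusted p = 0.25 each; edgeR adjusted p = 0.0556 and 0.0191). The cluster 7 difference of -0.567 points was -0.334 without control mouse 2. Cluster 2, of cycling cells, held 17.0% ± 2.17 and 21.9% ± 3.44 (exact p = 0.2). Its difference of 4.90 points was 3.07 without CAL-101 mouse 3, and 4.65 among clusters 1 to 5 (exact p = 0.1). At 1600 UMIs per cell, T cells with a UMI of Tcf7, a transcription factor of progenitor and memory T cells, and none of Havcr2, which encodes the inhibitory receptor TIM-3, made up 3.25% ± 1.21 in control and 10.9% ± 3.41 in CAL-101 tumours (exact p = 0.1). The same share in NK cells, which also express Tcf7, was 6.82% ± 0.891 and 6.87% ± 0.767 (exact p = 1), and among neutrophils 1 of 400 cells had such UMIs. T cells with Havcr2 and no Tcf7 made up 11.05% ± 5.15 and 7.64% ± 1.27 (exact p = 0.4), beside 3.97% and 4.15% of neutrophils. The difference of -3.41 points was -2.11, -6.37 and -1.74 without control mouse 1, 2 and 3. Without thinning the T cell shares were 9.81% ± 4.88 and 26.3% ± 6.32 for Tcf7 and 34.3% and 24.1% for Havcr2. Thinning left out 1181 control and 1434 CAL-101 T cells, and the median depths were 9136 UMIs in T cells, 6694 in NK cells and 3175.5 in neutrophils.

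In T cells, summed over all of them per mouse, cytotoxic effector genes were lower and several progenitor-associated genes were higher in CAL-101 tumours. Gzma, a granzyme of cytotoxic granules, fell from 1163 ± 74.2 to 174 ± 106 CPM (SD, n = 3 each; log2 -2.74, SE 0.37, edgeR adjusted p = 0.0026), and Serpinb9b, a serine protease inhibitor, from 104 ± 16.8 to 9.72 ± 1.99 CPM (log2 -3.42, SE 0.18, adjusted p = 7.56e-05). Tcf7 rose from 18.5 ± 6.67 to 72.7 ± 14.8 CPM (log2 1.98, SE 0.24, adjusted p = 0.00176), and Slamf6, a surface receptor of progenitor exhausted cells, from 11.8 ± 4.08 to 38.2 ± 7.18 CPM (log2 1.70, adjusted p = 0.0031). Tox, a transcription factor of exhausted T cells, rose in the same mice from 176 ± 16.3 to 690 ± 151 CPM (log2 1.98, SE 0.15, adjusted p = 0.000269). The immunoglobulin genes Jchain, Igkc and Ighm (log2 3.36, 3.24 and 1.71), Tcrg-C4, a gamma chain constant region (2.11), and the chemokine system genes Cxcr3 (1.82) and Cxcl10 (1.78) were among the other large increases. Tox, Jchain and Igkc lead cluster 5. Among the largest decreases were Gzmf (-3.18) and Gzme (-2.40), granzymes of the same gene cluster, the chemokine gene Ccl1 (-2.60, adjusted p = 0.0203), the potassium channel gene Kcnk10 (-2.57), Gipc2 (-2.38) and Anxa1 (-2.26). Gzmb fell from 1962 ± 528 to 868 ± 180 CPM (log2 -1.18, SE 0.22, adjusted p = 0.00869). Havcr2 was at 82.3 ± 35.5 and 54.7 ± 10.8 CPM (log2 -0.59, SE 0.31, adjusted p = 0.227), Ifng at 481 ± 128 and 368 ± 4.2 CPM (-0.39, adjusted p = 0.132) and Pdcd1, which encodes PD-1, differed by 0.06 (adjusted p = 0.671), none of them past the threshold. In all, 3194 of 16734 genes passed, 1583 higher and 1611 lower, and 2850 did in clusters 1 to 5, of which 2672 were shared; there Gzma differed by -4.40 and Tcf7 by 2.27. The groups did not overlap at 38.7% of genes, where chance gives 10%. Without control mouse 1, control mouse 3 or CAL-101 mouse 3 the count was 1712, 1429 or 1640. Igkc in T cells lost its call without control mouse 1 (2.97) or CAL-101 mouse 3 (3.26) and Ccl1 in T cells without CAL-101 mouse 2 (-2.43) or 3 (-2.41) and was at -1.60 without control mouse 2, while Havcr2 in T cells passed without control mouse 2 (-0.91) and Ifng in T cells without control mouse 1 (-0.55).

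**Figure D2:**
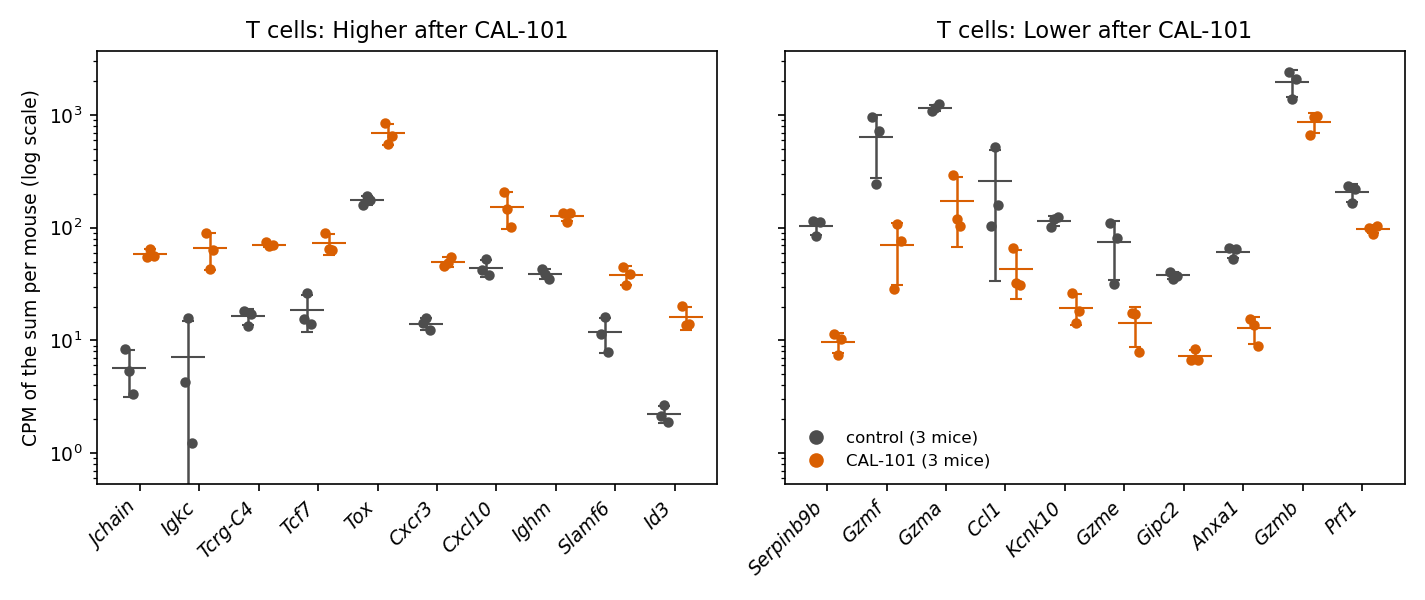
Expression of named genes in T cells (CPM of the summed counts of each mouse, log axis; points are mice, bars the mean and SD of 3) in control and CAL-101 tumours. Tcf7, Slamf6, Tox and the immunoglobulin genes were higher, and Gzma, Gzmb and Serpinb9b lower, in all CAL-101 mice; the control SD of Igkc (7.13 ± 7.74 CPM) runs below the axis.

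By gene list, the effector and cytotoxic list fell in T cells: 10 of 17 measured members were lower and 0 higher (10 adjusted over the list alone), with a mean log2 of -0.69 (camera adjusted p = 2.47e-09, and adjusted p = 0.0454 with an estimated correlation). Besides Gzma and Gzmb, these included Prf1, the pore-forming protein of cytotoxic granules (-1.09, adjusted p = 0.0016), Ccl5 (-1.31, adjusted p = 0.000578) and Zeb2, a regulator of terminal effector cells (-1.14, adjusted p = 0.000307). NK cells, which express these genes strongly, were among the T class, and in clusters 1 to 5 the list mean was -0.78. The proliferation list rose, 10 of 16 members higher (12 adjusted over the list alone), with Cdk1 at 0.42 and Nusap1 at 0.34 (camera adjusted p = 1.3e-05, but adjusted p = 0.617 with an estimated correlation). The type I interferon list rose, 8 of 15 members higher (10 adjusted over the list alone), with Usp18 at 1.06 and Ifit1 at 1.09 (camera adjusted p = 6.03e-05, but adjusted p = 0.617 with an estimated correlation). The progenitor exhausted list moved both ways, 7 members higher and 5 lower of 15 (7 and 5 adjusted over the list alone; camera adjusted p = 0.0839). Tcf7, Slamf6, Id3 (2.85), Cxcr5 (1.16), S1pr1 (0.57) and Klf2 (0.36) were among the higher, while Bach2 (-0.69), Lef1 (-0.84), Ccr7 (-1.42) and Il7r (-0.62), also genes of naive and memory cells, were among the lower. The terminally exhausted list had 3 higher and 3 lower of 16 (3 and 3 adjusted over the list alone; camera adjusted p = 0.558): Tox and Cd101 (0.61) were higher, and Lag3 (-0.43) and Cd244a (-0.70) lower. Cd244a in T cells lost its call in clusters 1 to 5 (-0.61, adjusted p = 0.223) and without control mouse 1 (-0.61), control mouse 3 (-0.63) or CAL-101 mouse 3 (-0.62).

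Among the other lists in T cells, none passed camera. The FOXO1-associated list had 6 higher and 4 lower of 14 (adjusted p = 0.448), with Foxo1 itself at 0.47 and Pik3ip1, an inhibitor of phosphoinositide 3-kinase, at -0.73. Of the metabolic lists, glycolysis had 1 higher and 2 lower of 15, oxidative phosphorylation 2 higher of 24, fatty acid oxidation 2 lower of 13, cholesterol synthesis 3 higher of 15, and hypoxia 4 lower of 14, with Ndrg1 at -0.94 (camera adjusted p = 0.263, 0.461, 0.0921, 0.0824 and 0.0824). Interferon gamma response had 4 higher and 2 lower of 19, MHC class II presentation 2 lower of 7, MHC class I presentation 2 higher of 10, and inflammatory cytokines 1 higher and 3 lower of 13 (adjusted p = 0.642, 0.0855, 0.461 and 0.263). Dissociation and stress genes had 6 higher and 1 lower of 14 (adjusted p = 0.0824), the macrophage and tissue repair list 2 higher and 3 lower of 9 (adjusted p = 0.968), and mitochondrially encoded genes 0 of 13 by edgeR (adjusted p = 0.461). Melanoma genes had 1 higher of 7 and endothelial genes 1 higher of 3 (adjusted p = 0.151 and 0.461). The fibroblast, keratinocyte and red cell lists had 0, 2 and 2 measured members and were not tested. The median and mean differed in sign for the terminally exhausted (-0.01 and 0.05) and endothelial (-0.06 and 0.23) lists, and camera ranked the macrophage list down although its mean was 0.56. Adjusted over the list alone, the counts were the same except for glycolysis (1 higher, 3 lower), interferon gamma response (5 and 3), macrophage (3 and 3) and dissociation (7 and 2). Fry adjusted p was under the threshold for the effector list (0.0014), fatty acid oxidation and dissociation (0.0494 each). Without control mouse 2, control mouse 3 or CAL-101 mouse 1, camera called 8, 5 or 6 lists in place of 3. Other divisions of the 6 mice into 3 and 3 gave 4 to 9 camera calls, so the number of lists called does not set the real groups apart.

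Surface proteins of T cells differed as well, with the costimulatory receptor GITR (CD357) showing the smallest p. Its share of antibody tags was 5.91% ± 0.460 in control and 2.54% ± 0.0815 in CAL-101 T cells (SD, n = 3 each; log2 -1.37, SE 0.07, edgeR adjusted p = 0.000171), and its transcript Tnfrsf18 fell by 0.86. Log2 values of tags come from TMM-scaled counts and so differ from the ratios of the printed shares. CD73, the ecto-enzyme that makes adenosine, rose from 0.118% ± 0.0198 to 0.360% ± 0.0633 of tags (log2 1.46, SE 0.17, adjusted p = 0.00647), and its transcript Nt5e by 1.48. CD5, an inhibitor of T cell receptor signalling (0.77), CD200 (0.73), the integrin CD49d (0.56), Tim-4 (0.37) and Ly108, the product of Slamf6 (1.73, adjusted p = 0.0374), were also higher. Ly108 differed by 0.95 (adjusted p = 0.0215) without cells of over 20000 tags. CD49b (-1.39), CD11c (-1.25), B220 (-1.07), CD61 (-0.87), CD55 (-0.87), the interleukin 2 receptor CD25 (-0.79) and the activation and memory marker CD44 (-0.63, adjusted p = 0.011) were lower. CD49b is an NK cell marker, and B220 took 1.57% of tags in control NK cells. In clusters 1 to 5 B220 differed by -0.54 (edgeR adjusted p = 0.061). CD55 took 8.88% of tags in cluster 7 and 0.166% in T cell cluster 1, CD61 6.87% and 1.89%, and CD11c 0.404% and 0.125%. Cluster 0, led by NK cell genes, held 6.01% of the T class in control and 2.30% in CAL-101 tumours. NK cells in the T class may therefore have given part of these falls. In T cells of clusters 1 to 5, edgeR called 8 antibodies lower in place of 15, and 9 higher in place of 7. These counts do not give the share of each fall that NK cells made. The CD44 transcript differed by 0.24 (adjusted p = 0.0633), against the direction of the protein. PD-1 (CD279; 0.10, adjusted p = 0.476), TIM-3 (CD366; -0.31, adjusted p = 0.384) and CD127 (0.06, adjusted p = 0.478) did not pass. In all, 22 of 102 antibodies passed, 7 higher and 15 lower, with no isotype control among them (edgeR; 33 at an unadjusted p under 0.05, DESeq2 38 antibodies). Scaled to the isotype controls 11 did, 3 higher and 8 lower, in clusters 1 to 5 alone 17, 9 higher and 8 lower, and with cells of over 20% mitochondrial or under 1000 UMIs left out 15, 7 higher and 8 lower. CD106 and CD4 were among the antibodies below the highest isotype control, at 0.70 and 0.746 of it. The count was 10, 11 and 13 without control mouse 1, 2 and 3, and 7 and 3 without CAL-101 mouse 2 and 3.

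**Figure D3:**
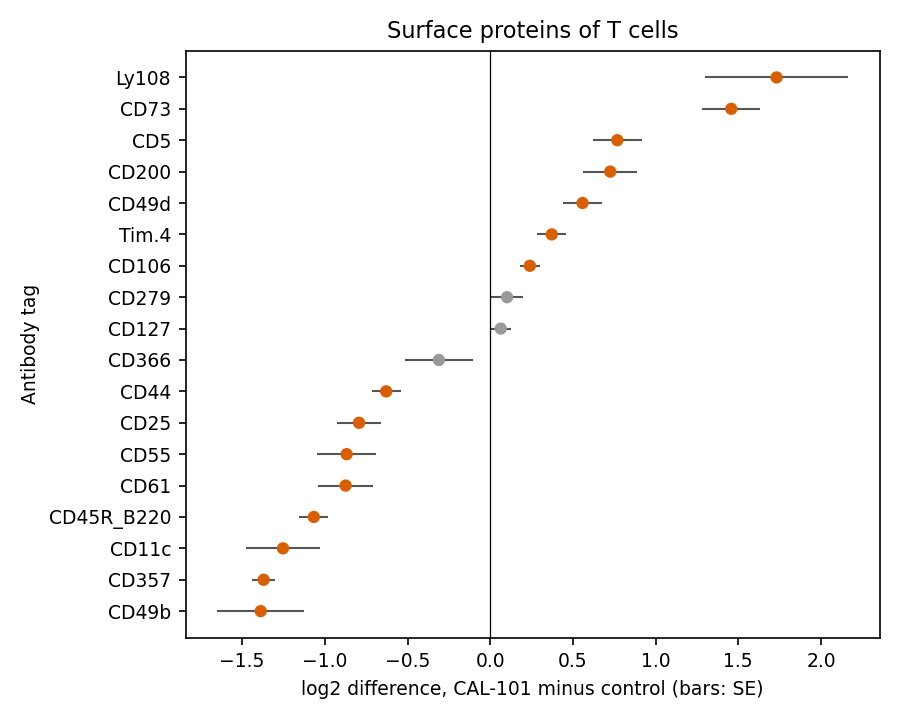
Log2 difference by edgeR on TMM-scaled counts (CAL-101 minus control, 3 mice each, bars are the SE) of the antibody tags of named surface proteins in T cells, orange where past the threshold and grey where not. Ly108 (1.73) and CD73 (1.46) stood highest and CD49b (-1.39) and CD357 (-1.37) lowest, and CD279, CD127 and CD366 did not pass.

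The host NK cells never met the drug, and their comparison asks about the surroundings of the transferred cells. In NK cells, Cirbp, a cold-inducible RNA-binding protein, fell from 129 ± 3.52 to 63.8 ± 5.08 CPM (SD, n = 3 each; log2 -1.01, SE 0.07, edgeR adjusted p = 0.000459). The chaperone genes Hspa1a (1.37, adjusted p = 0.0276), Hspa1b (1.33) and Hsph1 (0.92) were higher, while the dissociation and stress list, which holds the first pair, had 3 higher and 1 lower of 14 members (3 and 2 adjusted over the list alone; camera adjusted p = 0.364). In NK clusters 0, 7, 9 and 13 that list had camera adjusted p = 0.0497, but adjusted p = 0.753 with an estimated correlation. Also higher were the chemokine gene Xcl1 (0.91, adjusted p = 0.0375), Pclaf (0.88), Rrm2 (0.87) and Srm (0.86). Poln (28.5 and 14.5 CPM), Gstp3 (-0.97), Qrfp (-0.93), Wdr95 (-0.88), Nrgn (-0.82), Epb41l4aos (-0.79) and Camk4 (-0.74) were lower, as were Il7r (-0.89), Ccr7 (-0.89) and Pik3ip1 (-0.99). The proliferation list rose, 12 of 16 members higher (16 adjusted over the list alone), with Cdk1 at 0.89 and Top2a at 0.85 (camera adjusted p = 8.13e-23, but adjusted p = 0.719 with an estimated correlation). In NK clusters 0, 7, 9 and 13, Cdk1 differed by 0.37 (adjusted p = 0.259), and 1 of the 16 members passed. Cluster 8, led by NK receptor and granzyme genes with 1 histone gene, Hist1h1b, and not among those 4, held 5.43% ± 1.39 of NK cells in control and 10.1% ± 0.218 in CAL-101 tumours (exact permutation p = 0.1, adjusted p = 0.233). In control NK cells the mean log2 CPM of the proliferation members was 7.76 in cluster 8, against 4.37 in cluster 0 and 4.93 in cluster 7. Of the 1417 cells of cluster 8, 597 were labelled T cells and 45.8% were among the highest Scrublet scores. Without the highest scores, 12 of the 16 proliferation members passed in NK cells. Camera also called the mitochondrially encoded (3 of 13 higher), melanoma (3 of 5), cholesterol synthesis (0 of 15 by edgeR) and type I interferon (1 of 15) lists, with adjusted p = 9.32e-05, 0.000667, 0.00816 and 0.0168. Over each list alone the counts were 6, 5, 0 and 7, and each of these lists had adjusted p = 0.825 with an estimated correlation. Cluster 6, led by haemoglobin and mitochondrial genes, with a median of 34.9% mitochondrial UMIs, held 2.56% ± 0.775 of NK cells in control and 7.02% ± 3.47 in CAL-101 tumours, with no overlap (exact permutation p = 0.1, adjusted p = 0.233). Cluster 9 was lower, at 7.68% ± 0.359 and 5.35% ± 0.578 of NK cells, also with no overlap (exact permutation p = 0.1, adjusted p = 0.233). The cholesterol call was lost without control mouse 1 or CAL-101 mouse 2 (list means 0.14 and 0.20), and the interferon call without control mouse 2 or 3 or CAL-101 mouse 1 or 2 (0.14, 0.10, 0.16 and 0.14). The melanoma call was lost in the 4 NK clusters (list mean 0.20, camera adjusted p = 0.657), and its mean of 2.92 was 1.44 without CAL-101 mouse 1. The melanoma gene Dct was at 0.765 ± 0.149 and 11.8 ± 13.96 CPM, 27.8 CPM in CAL-101 mouse 1, and differed by -0.07 in the 4 NK clusters. Of the 17 effector and cytotoxic genes, 0 passed in NK cells by edgeR (0 adjusted over the list alone). In all, 686 of 14028 genes passed, 416 higher and 270 lower, with 213 in the 4 NK clusters. The count was 25, 1589 and 10 without control mouse 1, 2 and 3, and 146, 435 and 4 without CAL-101 mouse 1, 2 and 3. Of the 39 named calls, that of Cirbp alone held whichever mouse was left out, while Hspa1b ran from 0.96 to 1.61 and Rrm2 from 0.76 to 1.07. Of the surface proteins 1 passed: B220 was at 1.57% ± 0.0719 and 0.606% ± 0.0505 of tags (log2 -1.62 on TMM-scaled counts, edgeR adjusted p = 0.000882), while DESeq2 called 17, and 13 passed without CAL-101 mouse 1.

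Cells labelled monocytes, 34 to 101 per mouse, gave 0 of 5906 genes past the threshold by edgeR, with 182 at an unadjusted p under 0.05, 3 by DESeq2 and 2 without control mouse 2. The largest of the values was for Cacna1d, a calcium channel gene (log2 3.21, adjusted p = 0.293), and Il1b was at 4827 ± 4146 and 1662 ± 363 CPM. Camera called 9 lists there, among them MHC class II presentation, higher (adjusted p = 0.0028), and glycolysis and inflammatory cytokines, lower (0.00422 and 0.00646); each had adjusted p = 0.688 with an estimated correlation. The others were the terminally exhausted, melanoma, mitochondrially encoded and macrophage lists, higher, and the type I interferon and proliferation lists, lower, and 5 lists were called without control mouse 3 or CAL-101 mouse 1. Each of the 9 calls was lost without at least 1 of the mice. The label mixes clusters 10 and 11. Over all labels, cluster 10 held 322, 55 and 151 cells in the control mice and 29, 94 and 75 in the CAL-101 mice. Cluster 11 held 23, 47 and 25 in the control mice and 91, 33 and 41 in the CAL-101 mice. The list directions were not separated from a change in this mix. The MHC class II mean, 0.90, was 0.52 without control mouse 1 (adjusted p = 0.204) and 0.49 without CAL-101 mouse 1 (adjusted p = 0.0879), and glycolysis, at -0.41, lost its call without control mouse 2 (-0.22) or CAL-101 mouse 1 (-0.25). The inflammatory cytokine mean turned from -0.60 to 0.38 without control mouse 1, proliferation from -0.54 to 0.08 without control mouse 2, and the macrophage list from 1.05 to -0.04 without CAL-101 mouse 1. No surface protein passed by edgeR (12 at an unadjusted p under 0.05, 4 by DESeq2). By cluster number, cluster 10, led by neutrophil genes, had 308 of 5310 genes past the threshold, 136 higher and 172 lower. Its smallest p values belonged to Gzmf (-4.69), Ccl5 (-2.44), Tox (3.00) and Frmd5 (-6.06), of which Gzmf, Ccl5 and Tox moved in the same direction in T cells. The T cell genes Trbc2 (1.15), Cd8a (1.51), Bcl11b (1.60) and Themis (1.69) were also higher in cluster 10 (edgeR adjusted p = 0.0115 to 0.0169). Frmd5 and Ccl5 are among the leading genes of cluster 0, which is led by NK cell genes. RNA of T and NK cells in cluster 10 may therefore have given part of the 308 calls, which was not tested. Cluster 11, led by MHC class II genes, had 0 genes past the threshold by edgeR, with 446 at an unadjusted p under 0.05, and was not run with another tool.

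Over all sorted cells together, where changes in composition and in expression mix, 3118 of 17706 genes passed, 1584 higher and 1534 lower. Tox (log2 1.93, SE 0.08, edgeR adjusted p = 0.000625), the guanylate cyclase gene Gucy1b1 (2.72) and Id3 (2.71), an inhibitor of DNA-binding factors, were higher, and Kctd8, an auxiliary subunit of GABA-B receptors, lower (-3.10), with the smallest p values. The count was 1203 and 456 without control mouse 1 and 3, and 1335 and 950 without CAL-101 mouse 2 and 3.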

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

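The tests of T cells against NK cells and the tests of explanations were chosen after the results they bear on had been seen; only the bound on free NK cell RNA was written before its value was known.

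For 8 gene lists, limma camera at the preset correlation called a difference of effect between T cells and NK cells of the same mice, and none held with an estimated correlation (adjusted p = 0.726 for each). As T cells minus NK cells, the mean difference was -0.67 for the effector and cytotoxic list (adjusted p = 0.000105), -0.34 for proliferation (9.74e-05) and 0.33 for type I interferon response (0.000649). It was -0.18 for mitochondrially encoded genes (0.00925), 0.29 for FOXO1-associated genes (0.0271), -0.18 for glycolysis (0.0289), -0.39 for fatty acid oxidation (0.0386) and 0.38 for the progenitor exhausted list (0.0394). The fatty acid oxidation list includes Cd36, at 0.0176 and 1.42 CPM in control and CAL-101 NK cells. By gene, 576 of 13901 effects differed, 230 with a positive and 346 with a negative difference as T cells minus NK cells. The sign does not tell in which class the effect was stronger. Among them were Tcf7 (2.19), Tox (1.52), Gzma (-2.72), Prf1 (-1.22), Zeb2 (-1.19) and Top2a (-0.48). The other 9 splits of the 6 mice gave 0 such genes, but 3 mice against 3 allow only 10 splits, so a share under 0.05 cannot be reached.

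The lower effector and cytotoxic genes in T cells (10 of 17 members) were set against 3 technical explanations, and the tables argue against each as the whole cause. NK cells counted as T cells would leave few calls in clusters 1 to 5, where 9 members were still lower. Free NK cell RNA, at the median level of 6 NK markers in T cells of clusters 1 to 5, could give a median of 1.66% of the called members' CPM in control mice, and at most 11.1%, for Ccl5. At the level of Klre1, the highest of the 6 at 13.7% of its NK cell level, it could give all of Gzma and Ccl5, but 1 source would bring all 6 in 1 ratio, and Klra4, at 0.528%, allows at most 4.71%; of the 6, Klrb1c fell with treatment in these cells (-2.10, edgeR adjusted p = 0.00518). A change in the mix of the deposited clusters alone would leave no difference inside them, but 5 of 5 T cell clusters had members called lower and a negative mean, from -0.22 in cluster 5 to -0.88 in cluster 4. The list members Ccl3, Ifng and Ccl4 are themselves among the leading genes of cluster 3, and a graded shift of cells inside clusters was not tested. A handling difference between the groups was not among these explanations, and the labels give no processing batch. An effect of the CAL-101 culture on the cells remains a hypothesis, found and tested on the same mice.

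The higher proliferation genes in NK cells (12 of 16 members) were set against 3 explanations. The tables argue against a change in the mix of NK clusters as the whole cause and leave T cell RNA and doublets open. T cells counted as NK cells, or T cell RNA in them, were expected to raise T cell markers as much. The median log2 difference of 8 T cell markers was 0.114 (SD 0.22), below the median of 0.60 of the list by more than that spread, with Cd8a highest at 0.62 (edgeR adjusted p = 0.0568). The list also rose in T cells (mean log2 0.30), so T cell RNA could raise these genes more than the markers, and the comparison cannot decide. Doublets as the source were expected to take the calls with them, but 12 members passed without the cells of the highest Scrublet scores. That cut removed 2.49 to 3.28% of NK cells in CAL-101 mice and 3.21 to 5.29% in control mice. It left most of cluster 8 in place, so it cannot decide on doublets. A change in the mix of NK clusters alone would leave no difference inside clusters, but the list mean was 0.315 in cluster 0 and 0.46 in cluster 7, with every CAL-101 mouse above every control mouse; the mice overlapped in cluster 9 (0.46, 7 members measured, 0 called) and in cluster 8 (0.06), with 820 cells labelled NK and 597 labelled T, 45.8% of them among the highest Scrublet scores. Over clusters 0, 7, 9 and 13 the list mean was 0.34 (camera adjusted p = 2.74e-08, but 0.753 with an estimated correlation) and 1 member passed, against 0.62 in all NK cells. In control NK cells the list was at a mean log2 CPM of 7.76 in cluster 8, against 4.37 and 4.93 in clusters 0 and 7. Cluster 8 held 5.43% of NK cells in control and 10.1% in CAL-101 tumours. Its larger share may therefore give much of the rise in all NK cells, and an effect of the surrounding T cells is an untested hypothesis.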

How the results depend on the processing

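Alternatives by cluster, mitochondrial share, doublet score and tag limit were chosen after seeing the results. The others, leaving out mice included, were planned. The planned removal of called doublets was not run, since the automatic threshold marked 0 cells in some libraries. The cause of a change was not tested unless named.

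For T cells, 41 of 72 named calls kept direction and threshold under every alternative run and 0 reversed. For NK cells 1 of 39 did, and Dct (-0.0715) and Pmel (-0.0067) reversed in NK clusters 0, 7, 9 and 13. The count of T cell genes, 3194, was 1602 at a mean of at least 20 CPM, where fewer genes are tested, and 1369, 1771, 863, 953 and 624 in clusters 1 to 5 taken singly, with fewer cells. Leaving out 1 mouse gave 1429 (control 3) to 3850 (control 2), with 1712 without control 1 and 1640 without CAL-101 3. For NK cells, 686 became 1323 without a filter, 213 in the 4 NK clusters, and 4 (without CAL-101 3) to 1589 (without control 2), with 25, 10, 146 and 435 without control 1, control 3, CAL-101 1 and CAL-101 2. For cells labelled monocytes, 0 by edgeR (182 at an unadjusted p under 0.05) became 3 with DESeq2, 48 without a filter and 0 to 2 with 1 mouse left out (2 without control 2). For all cells, 3118 became 2018 at a mean of at least 20 CPM and 456 (without control 3) to 3727 (without CAL-101 1), with 1203, 1335 and 950 without control 1, CAL-101 2 and CAL-101 3.

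Lists called in T cells, 3, were 1 with an estimated correlation, 7 in clusters 1 to 5 and 3 to 8 with 1 mouse left out (8, 5 and 6 without control 2, control 3 and CAL-101 1). In NK cells, 5 became 0 with an estimated correlation and 0 with fry; in cells labelled monocytes, 9 became 0 and 0, and 5 to 10 with 1 mouse left out (5 without control 3 or CAL-101 1). There the inflammatory cytokine mean turned to 0.38 and camera's direction for type I interferon (mean -0.11) turned without control 1, proliferation turned to 0.08 without control 2, and the macrophage mean to -0.04 without CAL-101 1. Surface proteins of T cells, 22, were 11 scaled to isotype controls, 38 with DESeq2 and 3 (without CAL-101 3) to 18 (without CAL-101 1), with 10, 11, 13 and 7 without control 1, 2, 3 and CAL-101 2. In NK cells 1 became 17 with DESeq2, and 1 to 13 with 1 mouse left out (13 without CAL-101 1). In cells labelled monocytes 0 by edgeR (12 at an unadjusted p under 0.05) became 4 with DESeq2 and 1 without cells of over 20000 tags.

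With host cells as the denominator, the difference in the monocyte share reversed to 1.93 percentage points and that of dendritic cells was 1.39; the denominator is itself smaller where the T cell share is larger. With 1 mouse left out the monocyte difference ran from -0.311 to 0.0666, the latter without control 1. For cluster 5 the difference was 20.5 points in cells of at least 1000 UMIs and 22.1 in clusters 1 to 5; edgeR on cell numbers gave 3.25 for cluster 5 and -1.88 for cluster 3 (log2). The difference in the share of T cells in cluster 8, -0.831 points, reversed to 0.0957 without the highest Scrublet scores. Without thinning, the differences were 16.5 points for Tcf7 and -10.2 for Havcr2, since deeper cells show more UMIs.

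The replicate number as a block gave 1495 genes in T cells, 302 in all cells, 5 lists and 6 surface proteins in T cells, and within-number differences cannot go below an exact p of 0.25. Same-numbered mice did not deviate together (r = -0.48, -0.47 and -0.14 in T cells; 0.24, -0.00 and -0.22 in NK cells), so the samples share only a number. Not every mouse correlates best with its own number.

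The 6 mice make 10 splits into 3 and 3, the real one included, so no share under 0.05 can be reached. The real split and the highest other gave 3194 and 0 genes in T cells, 686 and 0 in NK cells, 3118 and 0 in all cells, 308 and 0 in cluster 10, 22 and 0 proteins in T cells and 1 and 0 in NK cells, each with 1 of the 10 splits as large. In cells labelled monocytes (0 and 0 genes, 0 and 2 proteins) and cluster 11 (0 and 29 genes), 10 of 10 splits gave as many. For camera lists the pairs were 3 and 9 in T cells (10 of 10 splits), 5 and 11 in NK cells (8) and 9 and 11 in cells labelled monocytes (4). The number of camera calls at the preset correlation therefore does not set the real groups apart, and why other splits give as many was not tested. In cells labelled monocytes, edgeR recovered 58% of simulated changes of log2 2 and 4% of those of log2 1.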

Other observations

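The tests of temperature and damage were chosen after the results they bear on had been seen.

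Immunoglobulin transcripts were among the largest increases in T cells, although 8 cells carried the B cell label. In cluster 5, Ighm was at 155 CPM, beside 0.598 CPM for Cd79a and 0.0498 for Ms4a1, both B cell genes. In NK cells Jchain was at 0.221 and 3.64 CPM in control and CAL-101 tumours (log2 3.98, edgeR adjusted p = 0.0148) and Igkc at 0.649 and 6.06 CPM (3.21, adjusted p = 0.000459), far below their T cell levels of 58.7 and 65.5 CPM in CAL-101 tumours. No explanation was tested.

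Of 5 genes chosen after the data were seen, the chaperone genes Hspa1a, Hspa1b and Hsph1 were higher and the cold-induced genes Cirbp and Rbm3 lower in both T cells and NK cells. The dissociation and stress list, fixed beforehand, did not pass camera in T cells (adjusted p = 0.0824) or NK cells (0.364). Hspa1a differed by 1.21 in T cells, 1.37 in NK cells and 1.71 in cluster 10, and Hsph1 by 1.04, 0.92 and 2.29. Cirbp differed by -0.73, -1.01 and -0.90, and Rbm3, another cold-inducible RNA-binding protein, by -0.56, -0.64 and -0.21.

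Handling or temperature of the tumours may have moved these genes in every cell type: in cluster 10, all 5 genes had the same sign and 2 of 5 passed the threshold, which leaves it open. T cell genes were also higher in cluster 10 (Trbc2 1.15, Cd8a 1.51), so T cell RNA there could carry the same signs. Damaged cells as the source are argued against, since 10 of 10 calls in T and NK cells held with cells of over 20% mitochondrial or under 1000 UMIs left out. The labels give no processing batch, so a handling difference and an effect of the transferred cells on the tumour cannot be told apart.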
